A study of Homo sapiens with 4 samples.

How the data were processed

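RNA that came down with Flag-tagged SIRT7 was compared with total input RNA in HEK293T, a human embryonic kidney line, made to express the tagged protein stably. RNA immunoprecipitation (RIP) recovers a protein with its bound RNA from a lysate, here with a gel that carries the anti-Flag antibody. Per the labels' protocols, the RNA was freed with proteinase K, ribosomal RNA was removed from input and RIP RNA alike, and strand-specific sequencing libraries were made. There were 2 input and 2 RIP libraries, placed in their groups by their titles. The labels do not say whether the 2 libraries of a group came from separate cultures. The p-values therefore measure the spread between these libraries, which the test pools in part over genes and which may be technical. No pull-down from cells without the tagged protein was analysed here, so RNA that binds the gel itself is part of the RIP values.

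Per the submitters' processing notes, cutadapt 1.5, Bowtie2 2.2.6, TopHat2 2.0.13 and Cuffdiff 2.2.1 were used with the genome build hg19. The gene annotation, the strand setting and the handling of reads with several positions are not given in the sources used here. One table held 23615 genes in 4 libraries. The deposited expected counts are the authors' estimated fragments per gene before scaling, and 97.94% of them were whole numbers. A second deposited column holds the same fragments as a scaled signal, divided by 1 factor per library between 0.93 and 1.1232. The deposited FPKM values are the authors' scaled fragments per kilobase of transcript and library size. The table named its libraries by condition and by a replicate number that starts at 0, so which library is replicate 1 of the labels rests on that numbering. It names the libraries left out in turn and enters only the fit with the number as a block. No column of other samples was present. The status column marked 12 of 94460 entries as failed, in 7 genes.

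The estimated counts were rounded to whole numbers. They summed to 18131602 and 17310755 fragments in input and to 25655456 and 25998032 in RIP. Fragments are not unique molecules, so depth bounds counting error only. Genes passing edgeR's filterByExpr at its defaults (a minimum count of 10 and a total of 15) were tested with edgeR 4.0.16 in R 4.3.3: TMM factors, glmQLFit and glmQLFTest with group as the only term, and Benjamini-Hochberg adjustment at 0.05. TMM factors were 1.298 and 1.278 in input and 0.7766 and 0.7759 in RIP. The standard error (SE) of a log2 fold change is its size divided by the square root of its F statistic. Levels are CPM on TMM-scaled library sizes, given as mean ± SD over the 2 libraries of a group.

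On counts simulated from the real means and depths for RIP against input (14465 genes), the test recovered 100% of genes raised 2-fold, 86% lowered 2-fold, 84% raised 1.5-fold and 88% lowered 1.5-fold, and 3.24% of its calls fell on unchanged genes. There only a small share of genes was changed, equally often up and down, with no length trend and a fixed spread between libraries. In the real data 77.7% of tested genes were called, so the simulation does not give the error share among the real calls. The 2 input libraries differed by more than sampling noise (6.17 chi-square per gene over 14429 genes with 20 or more fragments), as did the RIP libraries (3.40 over 13852 genes). All 4 were kept as separate samples. Such an excess can also be technical, so it does not show that the libraries came from separate cultures. The common coefficient of variation fitted by edgeR was 5.68%.

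Before the data were examined, 29 gene lists were fixed, written from the cell type, from the nucleolar deacylase SIRT7 and from the RNA classes such libraries hold. Lists with at least 3 tested members (22 lists) were tested with limma 3.58.1's camera on the edgeR fit, which asks whether a list moved relative to all other genes, at a preset inter-gene correlation of 0.01 and with Benjamini-Hochberg adjustment over the lists. An estimated correlation and the rotation test fry were the alternatives. The estimated correlation rests on the little spread that 4 libraries offer, and no list was called with it. Its lowest adjusted p was 0.385, also for a list with an estimated correlation below 0 (sirtuins, -0.153). It therefore decides neither for nor against a list. Counts adjusted over the list alone gave the same numbers of higher and lower members as adjusting over all genes in all 22 lists.

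Genes were named by a rule set at the same time: the sirtuins, the 12 genes with the largest change in each direction among those past the threshold with a mean of at least 50 counts and no overlap between groups (which chance gives 33.3% of genes in 2 against 2 libraries), the 2 most abundant and the 2 most significant members of each list, and the 5 genes with the largest share of counts in each group. The effective length of a gene was taken from the table itself, as scaled fragments over FPKM, in units of the median tested gene. It was had for 14543 of the tested genes. For a length-corrected fit, a smooth trend on log2 length (lowess, span 0.3) was put into each library's offsets. On simulated data with a length trend (14687 genes) the correction took the correlation with length from a Spearman rho of -0.98 to -0.05, left a true shift of a list at 0.50, and brought an unshifted ribosomal protein list from 1.87 to -0.01. The real trend was looser (rho -0.60). Only a single list was shifted, so the simulation does not show whether a rise shared by several short-gene lists would be kept.

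Other alternatives were RLE, upper-quartile and total-count scaling, DESeq2 1.42.0, limma-voom, limma on log2(FPKM + 1) and log2(FPKM + 0.1), other count filters, a replicate block, leaving out each library, small RNA genes, the 10 most abundant genes or genes with a failed status, and a 2-fold threshold. Gene symbols are those of the table. Of these, 20816 matched a current RefSeq symbol, 1793 an older one and 1006 none. The RefSeq table is of another build than hg19, so no coordinates were used here, and GC content was not tested.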

Results

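The study asked which RNAs are recovered together with SIRT7, a deacylase of the nucleolus and nucleus that removes acyl groups from lysines. RNA co-purified with Flag-SIRT7 (2 RIP libraries, 25655456 and 25998032 fragments on genes) was compared with total RNA of the same HEK293T line (2 input libraries, 18131602 and 17310755 fragments). Fragments were found on 17683 and 17375 genes in input and on 16846 and 16871 genes in RIP. Protein-coding genes held nearly all of them, 97.7% ± 0.141 (SD, n = 2) in input and 98.1% ± 0.0141 (n = 2) in RIP. The RIP libraries were concentrated on fewer genes: the 10 most abundant genes took 11.8% and 11.7% of the fragments in RIP, against 3.69% and 3.81% in input. Shares are given as values, because an exact two-sided permutation test of 2 against 2 libraries cannot go below p = 0.33.

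Among the genes counted, SIRT7 itself had the most fragments in the RIP libraries. Its mRNA rose from 0.15% ± 0.00136 (n = 2) of all fragments in input to 3.38% ± 0.0437 (n = 2) in RIP. In normalised counts this was 1165 ± 23.6 CPM against 43580 ± 537 CPM, a 37.4-fold rise (log2 fold change 5.23, SE 0.0779, edgeR adjusted p = 6.345e-16). The counts cannot separate the transgene from the endogenous gene. SIRT6, another chromatin-bound sirtuin, rose 2.93-fold (38.3 ± 1.08 against 13.1 ± 1.26 CPM), and the cytoplasmic tubulin deacetylase SIRT2 rose 2.22-fold. The mitochondrial SIRT3 rose 1.62-fold, and SIRT1 fell by 0.63 on the log2 scale. After length correction SIRT7 was at 4.63, SIRT6 at 0.89, SIRT2 at 0.73, SIRT3 at 0.66 and SIRT1 at -0.26. SIRT4 (log2 fold change 0.27, edgeR adjusted p = 0.3905) and SIRT5 (0.13, adjusted p = 0.2398) did not pass the test. After length correction they were at -0.72 (adjusted p = 0.03373) and 0.49 (adjusted p = 0.0001743). SIRT4 was at 0.435 without the first input library, 0.135 without the second and 0.163 without the second RIP library. With library totals in place of TMM factors, SIRT3, SIRT4 and SIRT5 had log2 fold changes of -0.038, -0.46 and -0.60, the last past the threshold. The sirtuins as a list stood above other genes (camera adjusted p = 0.00338, and adjusted p = 0.385 with an estimated correlation), and after length correction too (adjusted p = 0.000231), but with SIRT7 left out, a choice made after its value was seen, the adjusted p was 0.318.

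**Figure D1:**
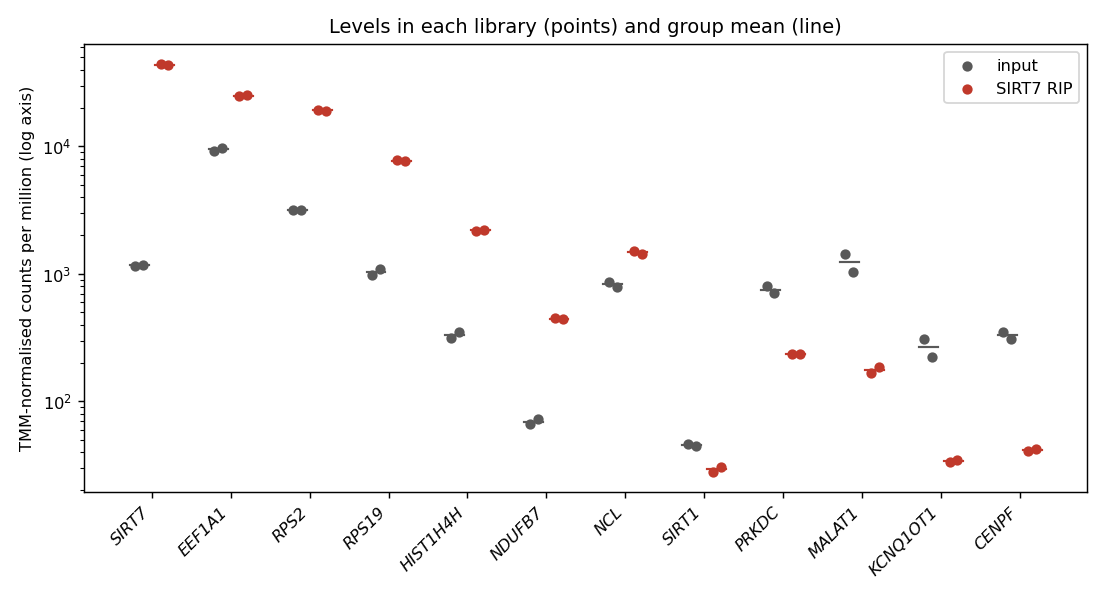
TMM-normalised CPM (log axis) of 12 genes in each of the 2 input (grey) and 2 SIRT7 RIP (red) libraries, with the mean of each group as a line. SIRT7 lies at 1165 CPM in input and 43580 CPM in RIP, while MALAT1, KCNQ1OT1 and CENPF lie lower in RIP than in input.

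The edgeR quasi-likelihood test was run on 14555 genes, of which 5532 were higher and 5783 lower in RIP than in input, with 3240 past neither side. At least 2-fold changes were found for 2550 genes higher and 2785 lower. Directions are relative to the TMM scale, on which the median gene had a log2 fold change of -0.03. Scaling by library totals only moved this median to -0.76 and turned the split of 48.9% higher calls into 20.6% (2479 higher and 9539 lower).

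Short mRNAs were high and long mRNAs low in the RIP libraries. Across 14543 genes the fold change fell with effective length (Spearman rho = -0.60, across genes, which are not independent replicates). Among the 1455 shortest genes 1164 were higher and 116 lower, with a median log2 fold change of 1.32. Among the 1455 longest genes 1239 were lower and 62 higher, with a median of -1.13. Taking this trend out with offsets left 5053 genes higher and 5179 lower, of which 7554 were called in the same direction as before and 1077 in the opposite one. Length-corrected values are therefore given beside the lists and most of the genes that follow.

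**Figure D2:**
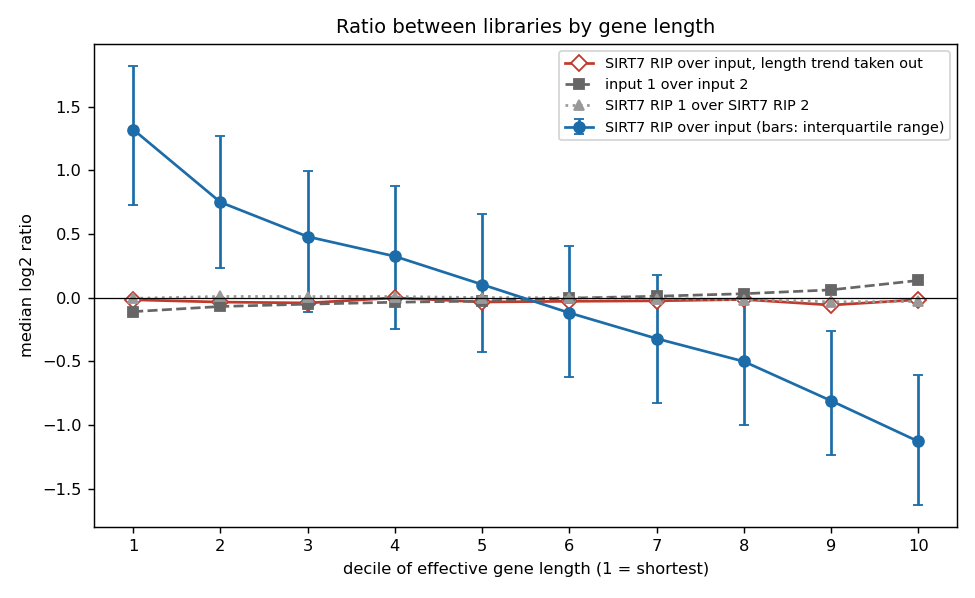
Median log2 ratio between libraries (y axis) in 10 bins of the tested genes by effective length (x axis, 1 is the shortest). RIP over input (blue, bars are interquartile ranges) runs from 1.32 to -1.13, its length-corrected form (red) stays near 0, and the ratios within the input pair (dark grey) and the RIP pair (light grey) run from -0.11 to 0.14 and from 0.00 to -0.03.

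Cytosolic ribosomal protein mRNAs grew from 8.80% ± 0.337 (n = 2) of all fragments to 19.8% ± 0.0212 (n = 2), and 81 of 83 tested members were higher and 1 lower (76 and 4 with library totals). RPS19 rose 7.44-fold, RPL35A 7.15-fold, RPSA 6.34-fold, RPS2 6.08-fold (3146 ± 3.49 to 19120 ± 52.6 CPM), RPLP0 6.04-fold and RPS6 2.46-fold. The list's median was 1.80 on the log2 scale (camera adjusted p = 1.26e-51). With an estimated correlation the adjusted p was 0.385. After length correction 51 were higher and 23 lower, the median was 0.25 and camera still called the list (adjusted p = 4.3e-06). Single genes then ranged widely, with RPS6 at -0.041 (adjusted p = 0.4433), RPS19 at 1.58, RPL35A at 0.99, RPSA at 1.58, RPS2 at 1.37 and RPLP0 at 1.61. Translation factors moved less as a list (36 of 51 higher, 7 lower, median 0.48, camera adjusted p = 0.000589, and adjusted p = 0.385 with an estimated correlation). Among them the elongation factor genes EEF1G, EEF1A1 and EEF2 rose 5.43-fold, 2.63-fold and 2.03-fold, and the initiation factor gene EIF3F 4.09-fold. EEF1A1 alone made up 1.22% ± 0.0341 of input and 1.94% ± 0.0291 of RIP fragments (n = 2 each). The translation factor median was 0.12 after length correction, with 25 higher and 14 lower (camera adjusted p = 0.0482), and EEF1G, EEF1A1, EEF2 and EIF3F were at 1.72, 1.61, 1.11 and 1.09. With library totals the list split into 14 higher and 32 lower, with a camera adjusted p of 0.131. Its median minus that of all genes stayed at 0.51.

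Replication-dependent histone mRNAs, which lack a poly(A) tail, rose from 1.76% ± 0.221 to 4.50% ± 0.177 of fragments (n = 2 each). Of 52 tested histone genes 51 were higher and none lower (50 and 1 with library totals), with a median log2 fold change of 2.12 (camera adjusted p = 6.33e-29, and adjusted p = 0.385 with an estimated correlation). HIST1H4H rose 6.60-fold, HIST1H3B 4.34-fold (927.6 ± 154 to 4023 ± 415 CPM) and the longer linker histone mRNA HIST1H1C 2.39-fold. Histone genes are close copies of one another, so the split of fragments between single members is uncertain. After length correction 30 were higher and 9 lower, the list's median was 0.25 and its call was lost (adjusted p = 0.0692), and HIST1H4H, HIST1H3B and HIST1H1C were at 0.58, 0.25 and -0.19.

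Nuclear-encoded mRNAs of mitochondrial proteins rose too. Of 80 oxidative phosphorylation genes 77 were higher and 2 lower (63 and 6 with library totals), median 1.59, camera adjusted p = 2.84e-35, and adjusted p = 0.385 with an estimated correlation. NDUFB7 of complex I rose 6.43-fold, UQCRB of complex III 5.28-fold and ATP5A1 of the ATP synthase 2.28-fold. Mitochondrial ribosomal protein genes were higher in 67 of 76 cases and lower in 2 (45 and 21 with library totals), median 1.14, camera adjusted p = 1.85e-17, and adjusted p = 0.385 with an estimated correlation, with MRPL23 at 5.77-fold and MRPL37 at 2.44-fold. After length correction the median of the oxidative phosphorylation list was 0.16, with 42 higher and 13 lower (adjusted p = 0.000991), and that of the mitochondrial ribosomal list 0.17, with 39 and 22 and no longer called (adjusted p = 0.194). NDUFB7, UQCRB and ATP5A1 were then at 0.96, 2.98 and 0.70, and MRPL23 and MRPL37 at 1.09 and 0.52. UQCRB had an effective length of 1.72 times the median gene, against a median of 0.226 for its list. Its corrected value depends on that length and is uncertain.

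Genes of factors that build ribosomes, a process SIRT7 takes part in, moved both ways. Of 59 ribosome biogenesis genes 39 were higher and 12 lower (13 and 33 with library totals), median 0.38, camera adjusted p = 0.0128. The H/ACA protein gene NHP2 rose 4.39-fold, the nucleolin gene NCL 1.79-fold and the nucleophosmin gene NPM1 1.38-fold, while HEATR1, which codes for a large processome protein, fell by 1.61 on the log2 scale. With an estimated correlation the camera adjusted p was 0.385, after length correction 0.0455, and with library totals 0.595, where NCL also lost its call (edgeR adjusted p = 0.1584). The list's median minus that of all genes stayed at 0.41 with library totals. NPM1 turned to -0.27 with library totals and to -0.33 after length correction. The length-corrected median was 0.19, with 32 higher and 16 lower, NHP2 at 0.82, NCL at 0.73 and HEATR1 at -0.49. RNA polymerase I subunit and factor genes were not called as a list (5 higher and 10 lower of 18, 2 and 16 with library totals, 7 and 6 after length correction, adjusted p = 0.568). The small subunit genes ZNRD1 and POLR1D rose 3.21-fold and 2.43-fold (0.29 and 0.08 on the log2 scale after length correction, which ended the call of POLR1D, adjusted p = 0.2883), whereas MYBBP1A and BAZ1B fell by 0.25 and 0.34 before and stood at 0.23 and 0.49 after length correction. MYBBP1A lost its call without the second RIP library (adjusted p = 0.1013).

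Other housekeeping lists were called higher too. Splicing factors and hnRNPs had 48 of 72 members higher and 14 lower (15 and 45 with library totals), median 0.43, camera adjusted p = 0.00338, with SNRPF at 4.09-fold and HNRNPA1 at 1.80-fold. Proteasome subunits had 28 of 35 higher and 3 lower (11 and 16 with library totals), median 0.71, adjusted p = 0.000107, with PSMB10 at 7.06-fold, PSMB4 at 2.14-fold and PSMA4 at 1.45-fold. The list of cytosolic chaperones and heat shock genes had 20 of 24 higher and none lower (3 and 16 with library totals). Its median was 0.50 (camera adjusted p = 0.00964), with HSPE1 at 2.45-fold and HSPA1B at 2.04-fold. Only 10 of the 23 snoRNA host genes in the table were tested. Of these 10, 7 were higher and 2 lower (5 and 4 with library totals), median 0.98, camera adjusted p = 0.00186. RPSA, named above with the ribosomal proteins, is also a host gene, so the host gene call is not independent of theirs. It was lost without the 10 most abundant genes (camera adjusted p = 0.101). With an estimated correlation the adjusted p was 0.385 for splicing factors, proteasome subunits and host genes and 0.389 for chaperones. After length correction none of these 4 lists was called. Splicing factors had 39 higher and 19 lower (median 0.20, adjusted p = 0.0522) and chaperones 12 and 2 (0.19, adjusted p = 0.215), while the direction of the others turned: proteasome subunits had 9 higher and 16 lower (-0.088, adjusted p = 0.655) and host genes 5 and 5 (-0.047, adjusted p = 0.908). With library totals the splicing and chaperone calls were lost (camera adjusted p = 0.301 and 0.304), as was that of HNRNPA1 (edgeR adjusted p = 0.09427). The medians of these 2 lists minus that of all genes stayed at 0.46 and 0.53. After length correction SNRPF was at 0.65, HNRNPA1 at 0.28, PSMB10 at 1.65, PSMB4 at -0.15, PSMA4 at -0.47 (-0.20 with library totals), HSPA1B at 0.83 and HSPE1 at 0.073, its call lost (adjusted p = 0.3337).

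Endoplasmic reticulum chaperone and translocon genes (21 higher and 11 lower of 35, adjusted p = 0.0668), immediate early genes (17 and 3 of 31, adjusted p = 0.208), sterol synthesis genes (11 and 4 of 22, adjusted p = 0.208) and cell cycle genes (20 and 9 of 38, adjusted p = 0.747) were not called as lists. The first was called without the first input library (adjusted p = 0.0485), without the second (0.0286) and with no count filter (0.046), and the immediate early list with no count filter (0.0321). With library totals the counts of higher and lower genes were 9 and 21, 5 and 11, 5 and 15, and 3 and 30, in the order given, and after length correction 17 and 8 (median 0.12), 9 and 6 (-0.033), 11 and 6 (0.14), and 18 and 12 (0.092). They held members that moved far: SEC61G, a small translocon subunit, rose 5.49-fold and JUND 3.28-fold (SEC61G was at 0.57 on the log2 scale after length correction). MCM2 of the replicative helicase rose 1.82-fold, a call lost with library totals (adjusted p = 0.06629) and at 1.07 after length correction. The mRNAs of the large kinetochore proteins CENPF and CENPE had log2 fold changes of -2.98 and -1.96, and of -1.70 and -0.84 after length correction. CANX, the calnexin gene, fell by 0.48 and was at 0.12 after length correction (adjusted p = 0.05284).

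Very long mRNAs were depleted. All 28 tested mRNAs of giant proteins were lower, median -1.64 (camera adjusted p = 4.26e-14, and adjusted p = 0.385 with an estimated correlation). The DNA-dependent protein kinase gene PRKDC fell from 750.4 ± 64.9 to 235.3 ± 2.70 CPM, and VPS13C and the ubiquitin ligase gene HUWE1 fell by 1.90 and 1.29 on the log2 scale. After length correction the list was at 0.04 with 12 members higher and 12 lower (adjusted p = 0.91), and PRKDC was at -0.17, VPS13C at -0.40 and HUWE1 at 0.29.

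Nuclear-retained long non-coding RNAs fell as a list: 6 of 9 were lower and 2 higher (7 and 0 with library totals), median -1.20 (camera adjusted p = 0.00338, and adjusted p = 0.385 with an estimated correlation). MALAT1, a speckle RNA, fell from 1236 ± 285 to 177.1 ± 13.3 CPM (log2 fold change -2.80, SE 0.121, edgeR adjusted p = 1.018e-11), and KCNQ1OT1 and TUG1 had log2 fold changes of -2.96 and -2.21. After length correction MALAT1 was at -1.66, TUG1 at -1.24 and KCNQ1OT1 at 0.02 (on the log2(FPKM + 1) scale without correction it was at -1.44). KCNQ1OT1 lies at the long end of the tested lengths (34.1 times the median gene). Its corrected value therefore rests on the end of the trend and is uncertain. The corrected list stayed below other genes with 4 lower and 1 higher (median -0.33, camera adjusted p = 0.0111). Without a count filter its call was lost (adjusted p = 0.0631). Genes of C2H2 zinc finger proteins, a large family of DNA-binding factors, were lower in 285 of 443 cases and higher in 75 (375 and 36 with library totals), median -0.79 (camera adjusted p = 0.000107, and adjusted p = 0.385 with an estimated correlation). ZNF24 fell by 0.94 and the short ZNF593 rose 5.04-fold. Length correction left 265 lower and 84 higher, median -0.52 (adjusted p = 0.000991), with ZNF24 at -0.09 (adjusted p = 0.2016) and ZNF593 at 0.77.

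**Figure D3:**
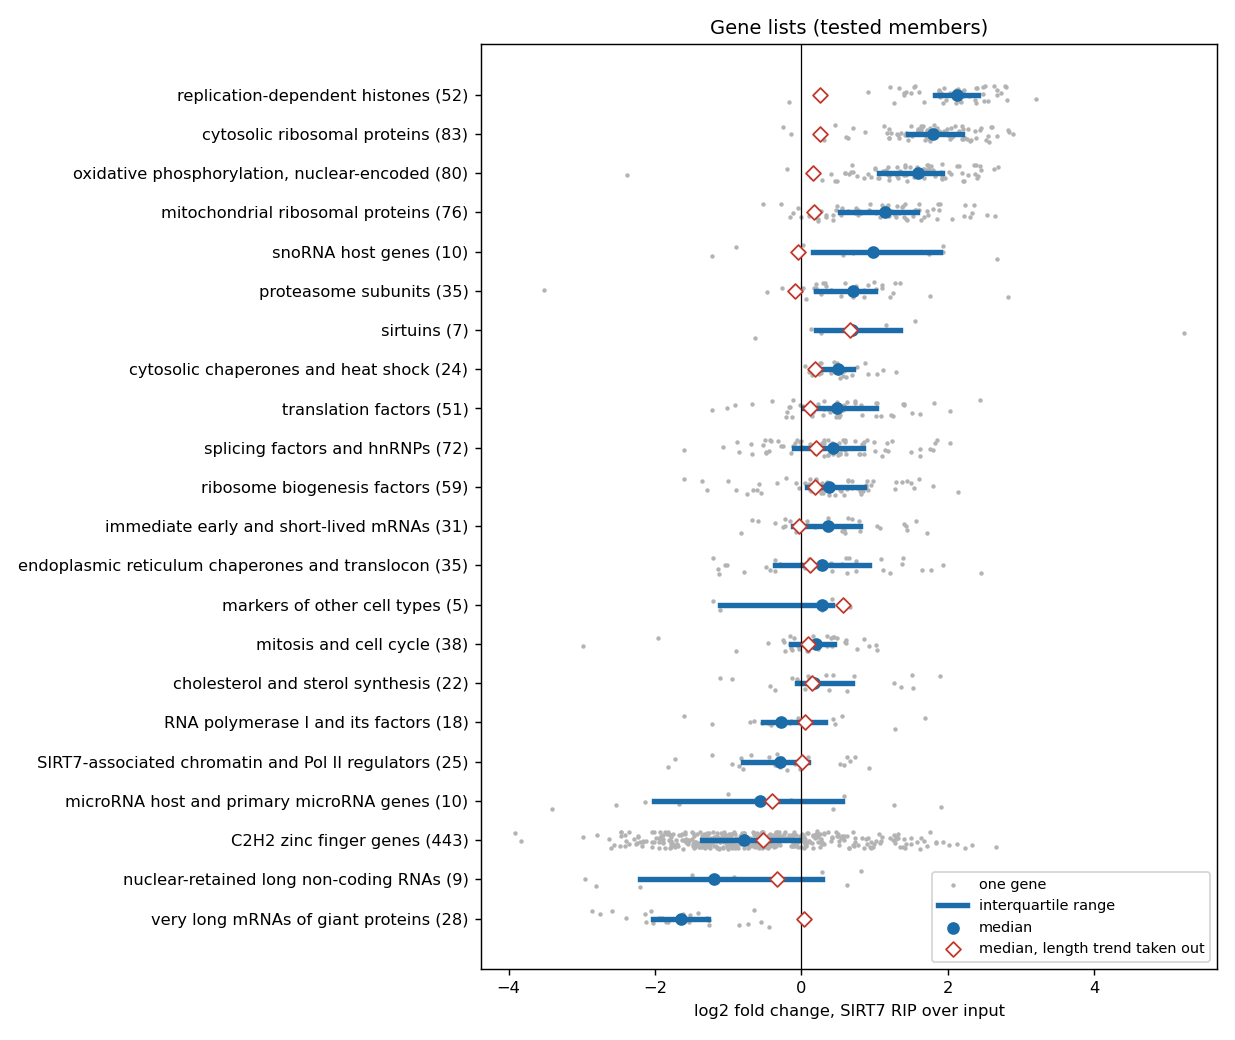
Log2 fold change of SIRT7 RIP over input (x axis) for the tested members (grey points) of the 22 gene lists (number of members in brackets), with the median and interquartile range (blue) and the median after the length trend was taken out (red diamonds). Histone, ribosomal protein and oxidative phosphorylation lists have medians of 2.12, 1.80 and 1.59 before and 0.25, 0.25 and 0.16 after, on the TMM scale, while with library totals the medians of the sirtuin, translation factor, ribosome biogenesis, splicing, proteasome, both chaperone, immediate early, sterol, cell cycle and other cell type lists turned negative.

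Genes of chromatin and RNA polymerase II regulators tied to SIRT7 were lower in 15 of 25 cases and higher in 6 (19 and 1 with library totals), with no call for the list (adjusted p = 0.0728, but 0.00571 with library totals, and a median of 0.0048 with 9 higher and 7 lower after length correction). Among them ELK4, a transcription factor known to bring SIRT7 to promoters, fell by 1.73 and the cyclin gene CCNT2 by 1.83, while the ubiquitin ligase adaptor gene DDB1 rose 1.90-fold. After length correction they were at -0.81, -0.88 and 1.39, and ELK4 was at -0.49 and -0.58 on the log2(FPKM + 1) and log2(FPKM + 0.1) scales. Of 1220 microRNA host and primary microRNA genes in the table only 10 were tested. The microRNA host list (2 higher and 5 lower of these 10, 2 and 6 with library totals, adjusted p = 0.715) was not called. Its median minus that of all genes turned from -0.54 to 0.092 without the first input library. After length correction it had 2 higher and 4 lower (median -0.40). Markers of other cell types were near the detection limit: 5 of 23 were tested, with no call for the list (adjusted p = 0.765). Their median log2 fold change was 0.28 and their mean -0.19, so median and test differ in sign. Length correction gave 2 higher and 2 lower (median 0.56). LYZ (2.88 ± 0.617 against 1.24 ± 0.695 CPM) and MBP (3.07 ± 0.135 against 1.42 ± 0.259 CPM) were lower in RIP, and COL1A1 did not pass the test (adjusted p = 0.09416), with 1.07 after length correction (adjusted p = 3.333e-06) and -0.45 with library totals (adjusted p = 0.0113). LYZ and MBP had log2 fold changes of -1.21 and -1.11, and of -1.95 and -0.60 after length correction. Without the first RIP library LYZ was at -0.73 and lost its call (adjusted p = 0.05217), and without the second it was at -1.92. On the log2(FPKM + 1) scale LYZ was at -0.70 and MBP at -0.37.

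Some of the largest single changes may rest on fragments shared between genes. Besides SIRT7, the neurotrophic factor gene METRN rose 7.87-fold (14.4 ± 2.40 to 112.9 ± 4.38 CPM), the polarity gene PARD6A 7.42-fold and FAM195B 7.31-fold (log2 values of 1.88, 1.95 and 1.85 after length correction). The highest folds belonged to names that join neighbouring genes, such as SYNJ2BP-COX16 (0.149 ± 0.21 to 11.1 ± 1.56 CPM) and TMEM189-UBE2V1 (0.407 ± 0.576 to 24.5 ± 0.949 CPM). Summed with both partner genes, their log2 fold changes were 0.39 and 0.31. Each was at 0 in 1 of the 2 input libraries, so values fitted with the other one left out rest on an input of 0 and are not given as folds. On the log2(FPKM + 1) scale they were at 2.70 and 3.06. Of 73 such tested genes 100% had fractional fragment estimates in at least 1 library, against 2.52% of other genes, so their values depend on how fragments were split and are uncertain. On the other side MARCH1, FSIP2 and the non-coding LUST had log2 fold changes of -4.10, -3.89 and -3.73 (-3.40, -2.02 and -4.57 after length correction). GOLGA8B, a gene with near-identical copies and so uncertain counts, was at -3.72 (-3.16 after length correction). On the log2(FPKM + 1) scale, which understates low genes, MARCH1, FSIP2 and GOLGA8B were at -1.42, -0.68 and -1.72. FSBP, which shares its locus with RAD54B, had no fragments in either RIP library and 4.66 CPM in input, at least 31.1-fold lower when 0 is set to 3 counts per library.

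Small structured RNAs were barely represented. The 2 ribosomal RNA genes and 24 Cajal body RNA genes in the table were listed at 0 in all 4 libraries, as were 248 of 252 C/D box snoRNAs, 100 of 105 H/ACA snoRNAs and 23 of 24 spliceosomal RNAs. The C/D box snoRNAs together had 3 and 1 fragments in RIP and none in input, and the H/ACA snoRNAs 2 and 3 against none. Of 10 RNA polymerase III transcripts only BCYRN1 was tested, and it fell by 0.96 on the log2 scale, with -4.20 after length correction. BCYRN1 lies at the short end of the tested lengths (0.0097 of the median gene). Its corrected value therefore rests on the end of the trend and is uncertain. No mitochondrially encoded gene was in the table. Because ribosomal RNA was removed from the libraries and nearly all snoRNA, Cajal body and spliceosomal RNA genes were listed at 0 in every library, these data cannot show whether SIRT7 carried such RNAs.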

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

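The read-through and SIRT7-free settings were chosen after seeing the data, all others before. RLE and upper-quartile factors, DESeq2, limma-voom, limma on log2 FPKM, other filters, omission of small RNA, abundant or failed-status genes and omission of single libraries kept the counts of higher and lower genes within 1.5 times of 5532 and 5783, with 5140 to 5527 and 5229 to 5580 when single libraries were left out. Same-numbered libraries did not deviate together (a correlation of 0.024 across genes). With a single difference per group, this shows no sign of a pairing but cannot exclude one. With the replicate block the counts of higher and lower genes were 5579 and 5860, with 11 lists higher and 3 lower as before. The block changed no call of the 71 named genes or 22 lists. Over all genes it shared 11286 of the 11315 calls. Library totals gave 2479 higher and 9539 lower, and a 2-fold threshold 2550 and 2785. Of 11 lists higher and 3 lower, library totals left 7 higher and length correction 5. An estimated inter-gene correlation left 0 higher and 0 lower, and fry, which does not compare a list with other genes, called 15 higher and 5 lower. Reversed with library totals were SIRT3 (-0.038), SIRT4 (-0.46), SIRT5 (-0.60), COL1A1 (-0.45), NPM1 (-0.27) and PSMA4 (-0.20), with SIRT5, COL1A1, NPM1 and PSMA4 past the threshold in that direction. For the uncalled lists of cell cycle, microRNA host and other cell type genes only camera's direction turned, while the medians minus that of all genes kept their sign (0.22, -0.54 and 0.31, and for the last 0.26 with no count filter). The microRNA host median turned to 0.097 with a mean of at least 50 counts and to 0.092 without the first input library. Reversed by length correction were SIRT4 (-0.72), HIST1H1C (-0.19), MYBBP1A (0.23), BAZ1B (0.49), KCNQ1OT1 (0.017), HUWE1 (0.29), PSMB4 (-0.15), RPS6 (-0.041), NPM1 (-0.33), PSMA4 (-0.47) and CANX (0.12), and the lists of snoRNA hosts (-0.018), proteasome subunits (-0.058), SIRT7-tied regulators (0.034), RNA polymerase I (0.077), immediate early genes (-0.0039) and very long mRNAs (0.066) on the same measure. For other cell types (0.59) only camera's direction turned. The corrected value of KCNQ1OT1 rests on the long end of the length trend and is uncertain. Leaving out the 10 most abundant genes ended the sirtuin and host gene calls (adjusted p = 0.317 and 0.101), since it removes members of both lists. Without a count filter the nuclear-retained list lost its call (adjusted p = 0.0631). The causes of the other changes were not tested. LYZ, a gene of a few CPM, had 15 and 35 fragments in the RIP libraries, and whether depth limits such genes was not tested.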

Other observations

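The tests of gene families by symbol, of SIRT7 against abundant genes and of long non-coding RNAs against matched genes were chosen after the data were seen, with the bounds of the last set before its result. Gene families outside the fixed lists were found by a shared symbol stem (155 families with 10 or more tested members). By camera on the edgeR fit, 6 families stood higher in RIP and 11 lower. The families were tested only at the preset correlation of 0.01 and not with library totals. With an estimated correlation, not run for families, no fixed list was called. The TIMM family of inner-membrane protein import was higher in 13 of 13 genes (median log2 fold change 1.06, adjusted p = 1.5e-05), LSM genes for RNA-binding rings in 10 of 12 (1.36, adjusted p = 0.00208) and TOMM genes of the outer import channel in 7 of 10 (0.86, adjusted p = 0.0121). GOLGA golgin genes were lower in 12 of 14 cases (-2.33, adjusted p = 0.000565), AKAP anchoring protein genes in 11 of 13 (-1.22, adjusted p = 0.000565) and centrosomal CEP genes in 26 of 30 (-0.79, adjusted p = 0.000565). After length correction GOLGA (-2.14, adjusted p = 0.000375) and AKAP (-0.59, adjusted p = 0.0239) were still called lower, whereas TIMM (0.42, adjusted p = 0.0665), LSM (0.097, 0.659), TOMM (0.25, 0.383) and CEP (-0.47, 0.0665) were not called. Of the other families, SETD stayed lower (-0.55, camera adjusted p = 0.0414). DHX was then called higher (0.62, 0.000375) and the LOC symbols lower (-0.61, 0.00892), both uncalled before (0.384 and 0.544). Several GOLGA genes are near-identical copies, so their counts are uncertain. Transcribed pseudogenes were lower in 182 of 319 cases and higher in 57, with a median of -0.88 that was -1.11 after length correction. Their share of all fragments went the other way, from 0.590% ± 0.0247 to 0.743% ± 0.0104 (n = 2 each), over all 786 such genes in the table. Pseudogenes resemble their parent genes, and the handling of reads with several positions is not given, so these counts are uncertain.

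The mRNA of SIRT7 rose far more than its length or abundance would give. Its log2 fold change was 4.63 after the length trend was taken out, against 5.23 before. Among the 145 other genes in the top 1% of input levels, the largest log2 fold change was 2.90, that of RPS19. Both values argue against length and high abundance as the whole cause. Transgene DNA in the RNA, binding of the mRNA to the gel and binding to SIRT7 complexes were not tested and stay open.

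The rise of ribosomal protein, histone and oxidative phosphorylation mRNAs went largely with gene length: after length correction their medians were 0.25, 0.25 and 0.16, from 1.80, 2.12 and 1.59. The last lay under the bound of 0.2 set for a length cause, and the others between that and the bound of 0.5 set against it. At the preset correlation of 0.01 camera still called ribosomal proteins (adjusted p = 4.3e-06) and oxidative phosphorylation (0.000991) but not histones (0.0692). With correlations estimated before the correction (0.438 and 0.464 for the 2 called lists) no list was called even without it (camera adjusted p = 0.385). The sirtuin list, with an estimated correlation of -0.153, had the same adjusted p. The estimated setting therefore decides neither for nor against a list. RNA integrity or fragment size of a preparation may contribute to the length trend, because the 2 input libraries also differed along length (Spearman rho = 0.34), although with a slope of 0.06 per doubling of length against -0.61 for RIP over input, and the RIP pair hardly did (rho = -0.074, slope -0.0088). A property of SIRT7 complexes and one of the pull-down stay open, since no pull-down without the tag was analysed here, and GC content was not tested.

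Long non-coding RNAs lay below protein-coding genes of like length and level. The median log2 fold change of 500 long non-coding RNAs was -0.11, against 0.19 on average over 10000 draws of protein-coding genes matched on length and input CPM (95% of draws between 0.08 and 0.32). The difference of -0.30 (-0.297) was outside the draws but just short of the bound of 0.3 set before the result was seen, so gene length and expression level were not excluded by that rule. The matched genes moved up, and the median of the 502 tested long non-coding RNAs went from -0.11 to -0.56 after length correction, against 0.0064 for protein-coding genes. The draws carry no error for the long non-coding median or for the small number of libraries. These values therefore do not settle the question. No biological explanation was tested.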
